A study of Mus musculus with 12 samples.

How the data were processed

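RNA was sequenced from 12 samples of mouse primary astrocytes, cultured from the midbrain of newborn mice labelled as wild type or as knockout of Arrb2, the gene of beta-arrestin 2. Each genotype received phosphate-buffered saline (PBS) or MPP+ at 500 µM for 24 h, and the labels give Day 14. MPP+ is the active metabolite of the toxin MPTP and inhibits complex I of the mitochondrial respiratory chain. The 4 groups hold 3 samples each. Per the labels, mixed glial cultures were shaken to remove other cell types, total RNA was extracted with TRIzol, and libraries were made with a SMARTER kit for mRNA sequencing. The labels name the genome builds GRCm38 and mm10. The aligner and the counting tool are not given in the sources used here.

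The deposited table holds raw counts per gene and sample, per the file headers, for 32742 Ensembl genes. It also holds FPKM values made by the authors, per the file headers. The values were checked: the counts are whole numbers with different totals per sample, and over 11408 genes with more than 200 counts in every library the ratio of count to FPKM, divided by its median in the library, lay between 0.998 and 1.00 at the outer percentiles examined. All 32742 gene identifiers were found in GENCODE release M21, with the same start for 32742 and the same end for 30042. Total counts ran from 64249029 to 69865569 per sample. No floor or interval below covers more than counting error, since reads without molecular identifiers are not independent molecules.

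Counts were fitted with edgeR 4.0.16 in R 4.3.3, with version 1.17.8 of the data.table package. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which left 21129 genes. Libraries were scaled by TMM, and a quasi-likelihood model with a mean for each of the 4 groups was fitted over all 12 samples with 8 residual degrees of freedom. The 5 contrasts were MPP+ against PBS in wild type, MPP+ against PBS in the knockout, knockout against wild type in PBS, knockout against wild type in MPP+, and the interaction, which is the MPP+ effect in the knockout minus that in wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 21129 genes of a contrast, with two-sided tests. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Levels are CPM with TMM-scaled library sizes. A fold against a group with 0 counts was computed against a floor of 3 counts over the 3 libraries of the group and is given as a lower bound. For a group with 1 to 3 counts the ratio is given with its counting interval. The log2 values for principal components used a prior count of 2.

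Gene lists were tested with camera of limma 3.58.1 on the same fit, with a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Lists with fewer than 5 tested members were described and not tested. Adjustment ran over the 32 functional lists of a contrast and, apart from these, over the marker lists. Member counts are given over all genes and adjusted over the list alone. The fry test of limma was run beside camera. The functional lists were mitochondrially encoded subunits of oxidative phosphorylation, nuclear complex I, nuclear complexes II to V, glycolysis, hypoxia response, amino acid response (Atf4 targets), endoplasmic reticulum chaperones, cytosolic and mitochondrial heat shock, Nrf2 targets, cholesterol synthesis, p53 targets, senescence-associated secretory factors, cell cycle, interferon response, NF-kappaB inflammatory genes, antigen presentation class I, complement, inflammasome and pyroptosis, JAK-STAT3 pathway, pan-reactive astrocyte, A1 reactive astrocyte, A2 reactive astrocyte, astrocyte identity and homeostasis, neurotrophic factors, autophagy, lysosome, mitophagy and mitochondrial dynamics, arrestins and G protein-coupled receptor kinases, dopamine receptors with monoamine metabolism and MPP+ transport, extracellular matrix, immediate early genes, and cytosolic ribosomal proteins. The 9 marker lists covered microglia and macrophages, the oligodendrocyte lineage, neurons, fibroblasts and meningeal cells, endothelial cells, pericytes and smooth muscle, ependymal and choroid plexus cells, red blood cells, and sex-linked genes. Of the 817 symbols in these lists, 814 were matched to the table, 5 of them through an older symbol, and 3 were not matched.

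The contrasts, the gene lists, the threshold, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The rule named Arrb2 and Arrb1, the 8 genes with the largest rise and the 8 with the largest fall among called genes with at least 2 CPM in the higher group and no overlap between the groups, and members of moved lists. The text gives a part of the genes so named. Genes of the mitochondrial ribosomal and transfer RNAs fall outside the rule and were chosen after their values were seen.

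The MPP+ effects of both genotypes, and the genotype effects of both treatments, were compared by correlation across genes, by the share of called genes with the same sign, and by the overlap of calls against the number that independence gives. The share of called genes within 10 Mb of Arrb2 was compared with that of all other tested genes by a two-sided Fisher's exact test, with windows of 5 and 20 Mb as alternatives. Other alternatives were size factors by relative log expression in edgeR, no filter, a stricter filter (mean FPKM of at least 5), a replicate block, only the samples of the compared groups, a 2-fold minimum, DESeq2 1.42.0, and limma on log2(FPKM + 1) of genes with FPKM of at least 1 in at least 3 samples. The limma fit was also run with a pseudocount of 0.1, no filter, the stricter filter, median-ratio rescaling, quantile normalization, a replicate block, no trend and sample weights. Each sample was left out in turn. After the data were seen, 3 alternatives were added: mitochondrially encoded genes left out, genes of X and Y left out, and the first replicate of both knockout groups left out. Some settings for the similarities, and limma fits that change 2 choices together, were added then as well.

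The procedure was tested on simulated data, with counts drawn from the wild-type PBS levels and the fitted spread of each gene, and changes planted in 1 knockout group. In a simulated comparison of the genotypes in PBS, edgeR called 98 of 19989 genes, of which 2.04% had no planted change, and it recovered 25.4% of 1.5-fold, 47.8% of 2-fold and 71.2% of 4-fold changes. In a simulated interaction it called 65 genes, of which 6.15% had no planted change, and recovered 2.99%, 26.9% and 62.1%. DESeq2 called 145 and 139 genes in the same data, of which 23.4% and 35.3% had no planted change. In both simulations camera called only the 1 list of 32 raised 1.5-fold. Genes were drawn without correlation, so its preset was untested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Nothing in the labels says that the replicates of a group came from separate cultures, so p-values measure the spread between samples only. Numbers of the replicates were not used as pairs outside the replicate block, since nothing in the labels pairs them. Reads were not used here.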

Results

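Total counts were compared over 12 astrocyte samples in 4 groups of 3. In units of 1 M counts the mean was 68.3 ± 1.11 (SD, n = 3) in wild type in PBS, 64.7 ± 0.592 in wild type in MPP+, 69.0 ± 0.700 in the knockout in PBS and 68.5 ± 1.65 in the knockout in MPP+. Between 23172 and 24706 genes had counts in a sample, and 21129 genes were tested. The first principal component held 51.1% of the variance and separated MPP+ from PBS in both genotypes. The second held 15.1% and separated the genotypes. Wild-type MPP+ replicate 1 stood apart from the other replicates of its group, with a score of 85.8 on the first component, where the others had 104.5 and 107, and of 34.4 on the third (5.28% of the variance), where they had -51.9 and -27.0. Values after ± are the standard error of a log2 fold change, n = 3 samples a group, unless SD is named.

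**Figure D1:**
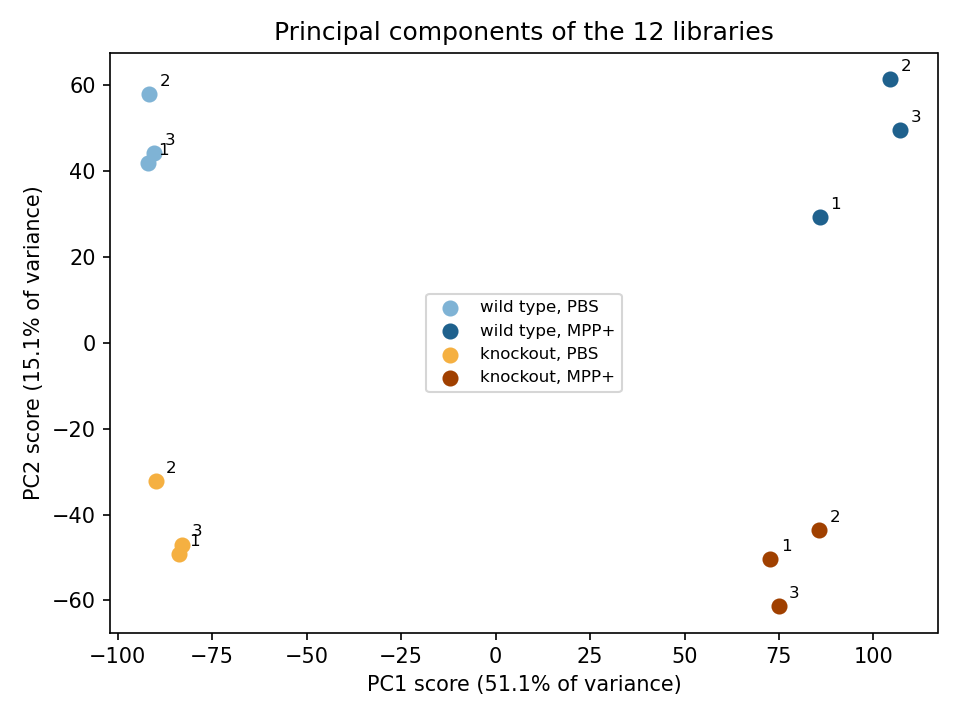
Scores of the 12 libraries on the first and second principal component of log2 CPM, with the replicate number beside each point. PBS libraries lie on the left and MPP+ libraries on the right, and wild-type MPP+ replicate 1 has a score of 85.8 on the first component.

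The knockout samples held less Arrb2 RNA than wild type, and RNA of the gene remained in each of them. Arrb2 (ENSMUSG00000060216, GRCm38 chromosome 11, 70432635 to 70440828, plus strand) encodes an adaptor that stops signalling of G protein-coupled receptors and carries them inward. Its level in PBS was 31.0, 26.4 and 21.7 CPM in the wild-type replicates 1 to 3, and 14.4, 16.1 and 13.8 CPM in the knockout. In MPP+ it was 24.2, 17.2 and 17.5 CPM in wild type and 15.1, 12.6 and 12.1 CPM in the knockout. The knockout minus wild type log2 difference was -0.83 ± 0.16 in PBS (adjusted p = 0.0084, edgeR quasi-likelihood test with Benjamini-Hochberg), and it stayed between -0.97 and -0.72, past the threshold, without any 1 library. In MPP+ it was -0.57 ± 0.16 (adjusted p = 0.0363), and this call was lost without each of 8 of the 12 libraries, with adjusted p up to 0.124. These 8 were wild-type PBS 2, wild-type MPP+ 1 and 3, all knockout PBS replicates and knockout MPP+ 2 and 3. Counts over a whole gene do not tell which exons the remaining reads came from.

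Arrb1, which encodes the related beta-arrestin 1, had 55.2 ± 3.66 CPM (SD) in wild type and 13.7 ± 0.633 CPM in the knockout in PBS. With MPP+ it had 23.1 ± 8.60 CPM in wild type and 20.8 ± 15.8 CPM in the knockout (replicates 37.6, 6.21 and 18.5 CPM). The PBS difference was -2.01 ± 0.49 (adjusted p = 0.0225), and -2.07 to -1.98 without any 1 library. The call was lost without wild-type PBS 2 or any knockout PBS replicate (adjusted p up to 0.0815). Its spread is pooled over all 4 groups, MPP+ included. In MPP+ the difference was -0.15 ± 0.47 (adjusted p = 0.875), and its sign turned without wild-type MPP+ 1 (0.13) and without knockout MPP+ 2 (0.28).

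The genotypes also differed in sex-linked RNA. Summed over Ddx3y, Eif2s3y, Kdm5d and Uty, 4 genes of the Y chromosome, the wild-type libraries held 0 to 0.230 CPM. The knockout replicates 1 to 3 held 39.4, 126.7 and 128.6 CPM in PBS, and 43.1, 131.2 and 129.4 CPM in MPP+. Eif2s3y was at least 1520-fold higher in the knockout in PBS, against a floor of 3 counts over the wild-type group. Xist, the RNA of the inactive X chromosome, was lower in the knockout, with -0.79 ± 0.14 in PBS and -0.74 ± 0.14 in MPP+, and it was present in each library at 393 CPM or more. Of the 5 tested sex-linked markers, 4 were higher and 1 lower in the knockout (4 and 1 adjusted over the list alone, adjusted p = 4.07e-09, or adjusted p = 0.00404 with an estimated correlation) in PBS. In MPP+, 4 were higher and 1 lower in the knockout (4 and 1 adjusted over the list alone, adjusted p = 9.5e-08, or adjusted p = 0.0338 with an estimated correlation). The sex of the animals and the genotype are therefore not separated by these samples.

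**Figure D2:**
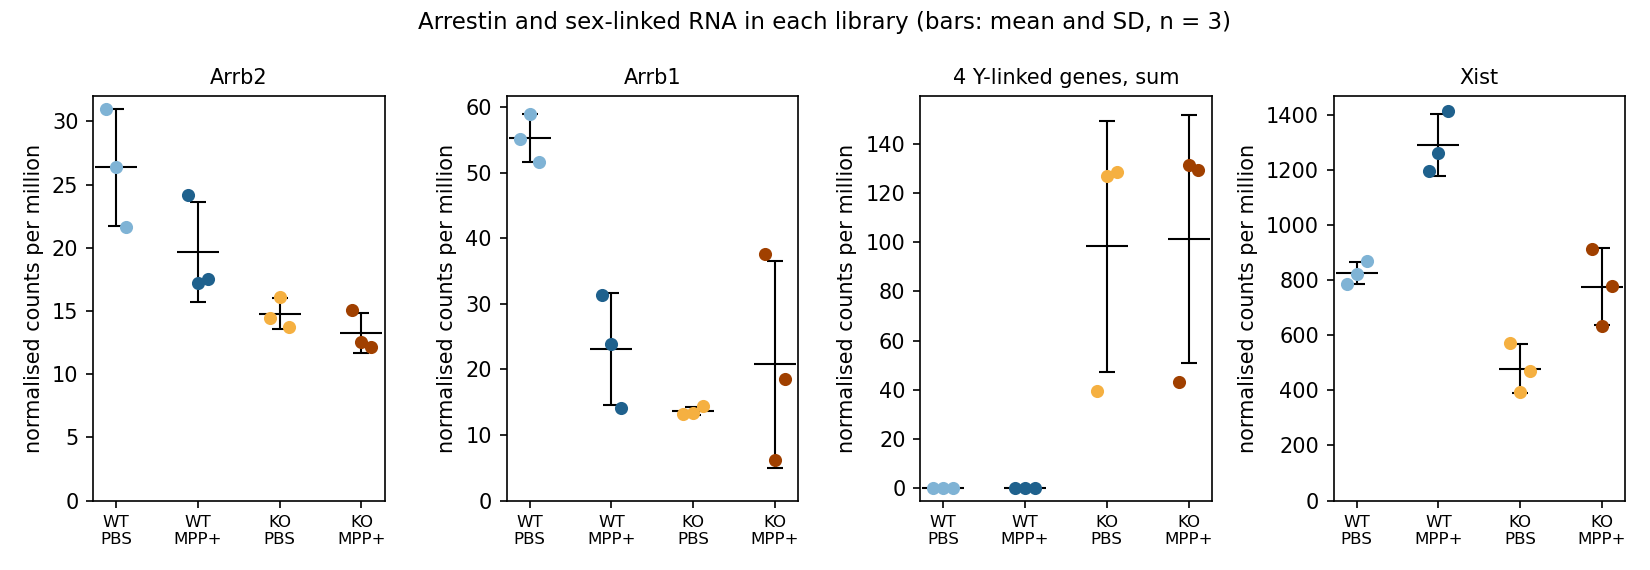
Normalised CPM of Arrb2, Arrb1, the sum of 4 Y-linked genes, and Xist in each of the 12 libraries, with the mean and SD of the 3 replicates of a group. Each knockout library has less Arrb2 than each wild-type library of its treatment, and Y-linked RNA is between 0 and 0.230 CPM in the wild-type libraries.

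The question put to MPP+ in wild type was what a day with this inhibitor of complex I changes in astrocyte cultures. Transcripts of the mitochondrial genome changed in opposite directions: mt-Co1, which encodes a catalytic subunit of cytochrome oxidase, fell with a log2 fold change of -3.94 ± 0.089, while the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 rose by 6.17 ± 0.19 and 6.79 ± 0.17. Targets of Atf4, the transcription factor of the integrated stress response, rose almost throughout, among them Ddit3 (4.45 ± 0.11), which encodes the stress factor CHOP. Genes of cell division fell, among them Mki67, a marker of cycling cells, with -5.03 ± 0.13. Gfap, which encodes the intermediate filament of astrocytes, fell with -3.47 ± 0.17. In all, 11667 of 21129 genes (55.2%) changed, 5656 higher and 6011 lower (48.5% higher, against 55.5% in limma on FPKM), and 5376 of them at least 2-fold.

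Large folds came from genes near 0 counts in PBS or in MPP+. Cox6a2, the muscle form of a cytochrome oxidase subunit, rose at least 799-fold, Adm2, a peptide hormone of the calcitonin family, at least 219-fold, and Ostn, a peptide made in bone and muscle, at least 196-fold, against floors of 3 counts. Otog, a protein of inner ear membranes, had 2 counts in PBS and rose 963-fold, with a counting interval of 267 to 7950. Hapln1, a link protein of the matrix around cells, had 0 counts in MPP+ and fell at least 220-fold. Steap4, a metal reductase, fell with -7.30 ± 0.62 and Slco1a1, an organic anion transporter, with -6.77 ± 0.55.

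Of the 13 tested messenger RNAs of the mitochondrial genome, 1 rose and 12 fell (1 and 12 adjusted over the list alone, adjusted p = 2.9e-12, or adjusted p = 0.149 with an estimated correlation). Those of complex I, the target of MPP+, included mt-Nd6 (-4.06 ± 0.14) and mt-Nd5 (-3.30 ± 0.12), and mt-Cytb of complex III fell with -2.08 ± 0.078. The member that rose was mt-Atp6, a subunit of ATP synthase (1.17 ± 0.33). Together these 13 held 6.08 ± 0.624% (SD) of the counts in PBS and 1.30 ± 0.178% in MPP+. The ribosomal RNAs held 0.0563 ± 0.00292% in PBS and 5.74 ± 1.27% in MPP+. The rise began at the start of the genome with the transfer RNA gene mt-Tf (8.52 ± 0.25), included mt-Tv (5.60 ± 0.39) between the ribosomal RNAs, and ended before mt-Tl1 (-1.56 ± 0.11), the gene next to mt-Rnr2. These transfer and ribosomal RNA genes were chosen after their values were seen.

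**Figure D3:**
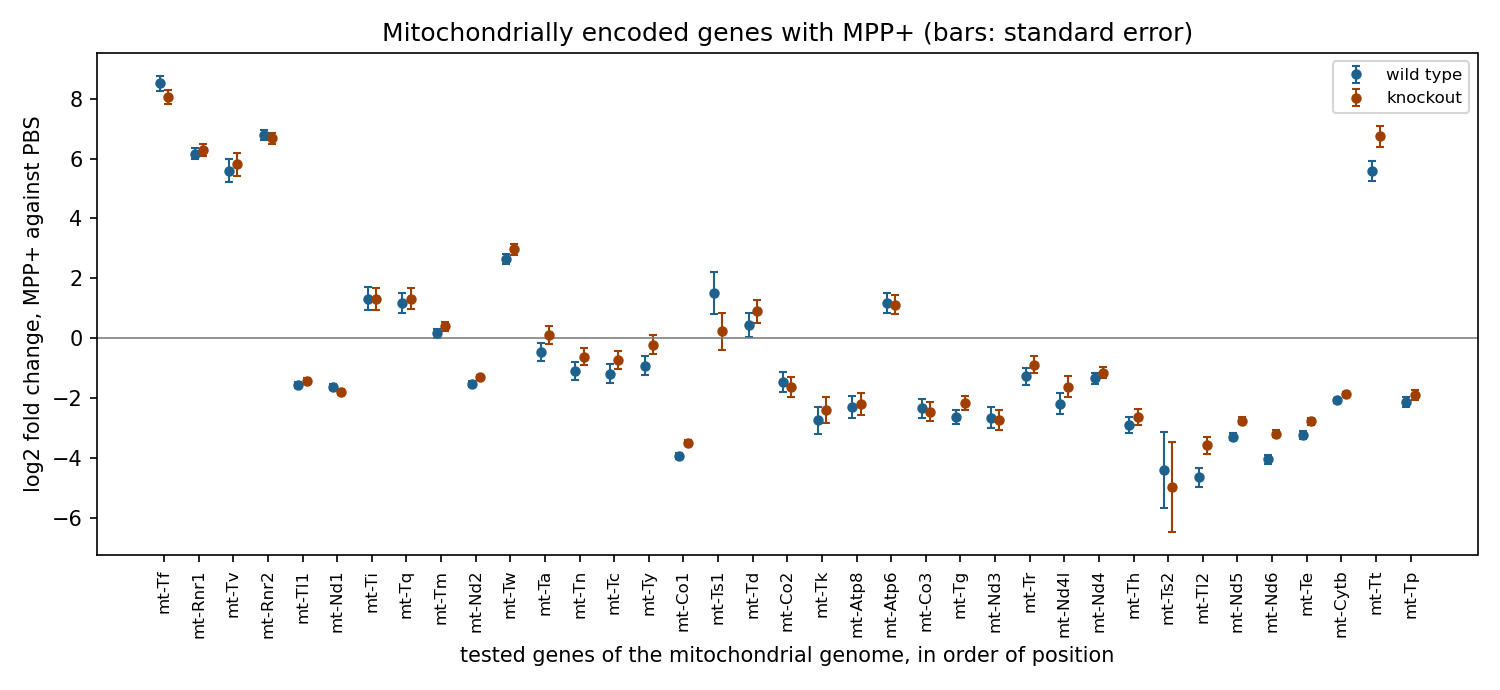
Log2 fold changes, with standard errors, of the tested genes of the mitochondrial genome with MPP+ against PBS in wild type and knockout, ordered by position. The ribosomal RNAs lie above 6 in both genotypes and mt-Co1 lies below -3.

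Genes of the nucleus for mitochondrial energy supply and glucose use differed by list. Of the 36 tested nuclear subunits of complex I, the target of MPP+, 12 rose and 8 fell (12 and 8 adjusted over the list alone, adjusted p = 0.842). Of the 39 tested subunits of complexes II to V, 2 rose and 23 fell (2 and 24 adjusted over the list alone, adjusted p = 0.0148, or adjusted p = 0.747 with an estimated correlation). Of the 20 genes of glycolysis, 2 rose and 13 fell (3 and 13 adjusted over the list alone, adjusted p = 0.00477, or adjusted p = 0.283 with an estimated correlation). Vegfa, a growth factor of vessels that low oxygen and stress raise, rose with 2.79 ± 0.070. The mitochondrial chaperone Hspa9 and the mitochondrial protease Lonp1 rose with 2.28 ± 0.044 and 2.16 ± 0.053.

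Of the 40 targets of Atf4, 39 rose and 0 fell (39 and 0 adjusted over the list alone, adjusted p = 9.34e-68, or adjusted p = 4.57e-05 with an estimated correlation). They included the amino acid transporter Slc7a5 (2.76 ± 0.073), the lipoprotein receptor Vldlr (3.53 ± 0.087) and the proline synthesis enzyme Aldh18a1 (2.22 ± 0.056). Of the 20 targets of the tumour suppressor p53, 18 rose and 1 fell (18 and 1 adjusted over the list alone, adjusted p = 4.3e-14, or adjusted p = 0.136 with an estimated correlation). The death receptor Tnfrsf10b (2.02 ± 0.089), the p53 inhibitor Mdm2 (1.73 ± 0.089) and the RNA-binding Zmat3 (1.65 ± 0.073) rose, and Sesn1 fell (-1.26 ± 0.068). Of the 24 targets of Nrf2, which governs defence against oxidants, 10 rose and 10 fell (11 and 10 adjusted over the list alone, adjusted p = 0.616). Hmox1, which breaks down heme, and the cystine transporter Slc7a11 rose with 2.30 ± 0.14 and 3.81 ± 0.26, and the peroxidase Prdx1 fell with -1.25 ± 0.073. Of the 31 lysosomal genes, 22 rose and 3 fell (23 and 3 adjusted over the list alone, adjusted p = 0.000417, or adjusted p = 0.577 with an estimated correlation), with the proteases Tpp1 (1.46 ± 0.069) and Ctsl (1.24 ± 0.067) among those that rose. Of the 24 immediate early genes, 10 rose and 4 fell (10 and 4 adjusted over the list alone, adjusted p = 0.0307, or adjusted p = 0.62 with an estimated correlation). Klf4 had 3.70 ± 0.23. Of the 44 cytosolic ribosomal proteins, 32 rose and 2 fell (32 and 2 adjusted over the list alone, adjusted p = 0.000505, or adjusted p = 0.721 with an estimated correlation). Rps3 had 0.76 ± 0.063.

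Of the 35 genes of the cell cycle, 0 rose and 32 fell (1 and 32 adjusted over the list alone, adjusted p = 2.9e-53, or adjusted p = 0.00271 with an estimated correlation). The mitotic activator Cdc20 had -3.93 ± 0.12 and the replication helicase subunit Mcm4 -2.01 ± 0.061. Of the 25 genes of cholesterol synthesis, 1 rose and 19 fell (1 and 20 adjusted over the list alone, adjusted p = 4.5e-05, or adjusted p = 0.187 with an estimated correlation). The synthase Hmgcs1 had -1.42 ± 0.057 and the sterol carrier Stard4 -2.25 ± 0.093. Of the 26 genes of astrocyte identity and homeostasis, 0 rose and 22 fell (0 and 22 adjusted over the list alone, adjusted p = 1.6e-19, or adjusted p = 0.128 with an estimated correlation). Glutamine synthetase, Glul, fell with -2.80 ± 0.074 and the water channel Aqp4 with -2.88 ± 0.094. Of the 13 pan-reactive astrocyte genes, which rise in many brain injuries, 1 rose and 10 fell (1 and 10 adjusted over the list alone, adjusted p = 3.94e-05, or adjusted p = 0.139 with an estimated correlation). The filament gene Vim had -1.40 ± 0.071. Of the 27 genes of the extracellular matrix, 2 rose and 14 fell (2 and 15 adjusted over the list alone, adjusted p = 0.0252, or adjusted p = 0.747 with an estimated correlation). The collagen Col11a1 had -3.15 ± 0.21.

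Markers of other cell types were measured beside these. Of the 18 tested markers of microglia and macrophages, 1 rose and 16 fell (1 and 16 adjusted over the list alone, adjusted p = 0.0184, or adjusted p = 0.587 with an estimated correlation). Lyz2, the lysozyme of these cells, fell with -1.52 ± 0.22, and Cd68, a protein of their lysosomes, rose with 1.36 ± 0.22. Of the 14 markers of the oligodendrocyte lineage, 0 rose and 6 fell (0 and 6 adjusted over the list alone, adjusted p = 0.00728, or adjusted p = 0.162 with an estimated correlation). Olig1 had -3.42 ± 0.11. Of the 13 neuronal markers, 0 rose and 7 fell (0 and 7 adjusted over the list alone, adjusted p = 0.00728, or adjusted p = 0.162 with an estimated correlation). The tubulin Tubb3 had -3.12 ± 0.15. Of the 8 markers of pericytes and smooth muscle, 2 rose and 5 fell (3 and 5 adjusted over the list alone, adjusted p = 0.00728, or adjusted p = 0.162 with an estimated correlation). The actin Acta2 had -2.20 ± 0.15.

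With an estimated correlation, 2 of the 13 functional lists called in wild type held, the Atf4 targets and the cell cycle genes. The extracellular matrix list was lost without wild-type PBS 1 (adjusted p = 0.102) and the immediate early genes without wild-type MPP+ 2 (adjusted p = 0.0556), and the falls of Arrb2 (-0.42 ± 0.16) and Arrb1 (-1.26 ± 0.48) with MPP+, at adjusted p = 0.0442 and 0.0422, were lost without 7 and 9 of the 12 libraries, with adjusted p up to 0.16 and 0.14. For Arrb2 the libraries were wild-type PBS 1 and 2, wild-type MPP+ 2 and 3, knockout PBS 1, and knockout MPP+ 2 and 3. For Arrb1 they were all wild-type PBS and all knockout PBS replicates, wild-type MPP+ 2 and 3, and knockout MPP+ 3. Under the alternatives, with camera at the preset correlation, the immediate early genes were lost in 9 of 17 (adjusted p up to 0.194), and the markers of the oligodendrocyte lineage and of neurons in 7 of 15 each (up to 0.178 and 0.141). Over all tested genes, 62.9% had every sample of a group above every sample of the other, where chance gives 10%.

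MPP+ in the knockout asked whether Arrb2-knockout astrocyte cultures respond to the toxin as wild type does. The mitochondrial ribosomal RNAs rose again, with mt-Rnr1 at 6.28 ± 0.19, mt-Rnr2 at 6.68 ± 0.17 and mt-Tf at 8.06 ± 0.24, and mt-Co1 fell with -3.49 ± 0.087. Ddit3 rose with 4.21 ± 0.11 and Trib3, a pseudokinase that Atf4 induces, with 6.67 ± 0.29. Of genes active in mitosis, Mki67 fell with -6.16 ± 0.14, Depdc1a with -7.51 ± 0.45 and the kinase Pbk with -6.61 ± 0.26. In all, 10083 genes (47.7%) changed, 4871 higher and 5212 lower (48.3% higher, against 58% in limma on FPKM), and 3968 at least 2-fold. Otog rose at least 974-fold, Cox6a2 at least 918-fold and Adm2 at least 293-fold.

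The effects in both genotypes went together. Across the 21129 genes the log2 fold changes had a Pearson correlation of 0.751 and a Spearman correlation of 0.810, where genes are not independent replicates. The Pearson value was 0.413 with no filter, 0.926 with the stricter filter and 0.851 with 2 groups only. Of the genes called in wild type 96.3% had the same sign in the knockout, and of those called in the knockout 97.4% had the same sign in wild type. Both calls were higher for 4205 genes, where independence gives 1304, both lower for 4428, where it gives 1483, and opposite for 25. Over 13092 genes the slope of the knockout effect on the wild-type effect was 0.817.

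Of the 13 mitochondrial messenger RNAs, 1 rose and 12 fell (1 and 12 adjusted over the list alone, adjusted p = 5.66e-13, or adjusted p = 0.147 with an estimated correlation). Their share of counts was 6.45 ± 0.802% (SD) in PBS and 1.55 ± 0.236% in MPP+, and that of the ribosomal RNAs was 0.0802 ± 0.000379% and 8.06 ± 0.927%. Of the 39 subunits of complexes II to V, 2 rose and 28 fell (2 and 28 adjusted over the list alone, adjusted p = 0.000254, or adjusted p = 0.736 with an estimated correlation). Of the 20 glycolysis genes, 2 rose and 14 fell (2 and 15 adjusted over the list alone, adjusted p = 0.000636, or adjusted p = 0.169 with an estimated correlation). Among the 40 targets of Atf4, 38 rose and 1 fell (39 and 1 adjusted over the list alone, adjusted p = 3.89e-84, or adjusted p = 3.7e-05 with an estimated correlation). Slc7a5 had 2.94 ± 0.074. Among the 15 heat shock genes, 7 rose and 7 fell (7 and 7 adjusted over the list alone, adjusted p = 0.0316, or adjusted p = 0.147 with an estimated correlation). The mitochondrial members Hspa9 (2.16 ± 0.044) and Lonp1 (2.05 ± 0.053) rose and the cochaperone Bag3 fell (-0.86 ± 0.082). Among the 20 targets of p53, 18 rose and 1 fell (18 and 2 adjusted over the list alone, adjusted p = 3.76e-08, or adjusted p = 0.169 with an estimated correlation). Zmat3 had 1.25 ± 0.072, Tnfrsf10b 1.31 ± 0.087 and Sesn1 -1.20 ± 0.068. Hmox1 rose with 2.38 ± 0.14 and Prdx1 fell with -0.93 ± 0.073. Among the 31 lysosomal genes, 21 rose and 3 fell (21 and 3 adjusted over the list alone, adjusted p = 0.000265, or adjusted p = 0.528 with an estimated correlation). Ctsl had 1.37 ± 0.068. Klf4, an early response gene, rose with 2.65 ± 0.21.

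Among the 35 cell cycle genes of the knockout, 1 rose and 32 fell (1 and 33 adjusted over the list alone, adjusted p = 2.26e-75, or adjusted p = 0.00142 with an estimated correlation). The topoisomerase Top2a had -3.88 ± 0.11. Among the 25 genes of cholesterol synthesis, 0 rose and 22 fell (0 and 22 adjusted over the list alone, adjusted p = 6.79e-11, or adjusted p = 0.0606 with an estimated correlation). Hmgcs1 had -1.52 ± 0.057 and Stard4 -2.19 ± 0.093. Among the 26 astrocyte genes, 0 rose and 21 fell (0 and 21 adjusted over the list alone, adjusted p = 3.19e-17, or adjusted p = 0.144 with an estimated correlation). Glul had -2.59 ± 0.073 and Aqp4 -2.77 ± 0.094. Among the 13 pan-reactive genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone, adjusted p = 0.000481, or adjusted p = 0.169 with an estimated correlation). Gfap had -3.04 ± 0.17. Stat3, a transcription factor of astrocyte reactivity, fell with -1.39 ± 0.10. Among the 27 matrix genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone, adjusted p = 0.0325, or adjusted p = 0.779 with an estimated correlation). For microglia and macrophages (18 tested), 1 rose and 12 fell (1 and 14 adjusted over the list alone, adjusted p = 0.0172, or adjusted p = 0.719 with an estimated correlation). Lyz2 fell with -1.72 ± 0.22 and Cd68 rose with 1.45 ± 0.22. For the oligodendrocyte lineage (14 tested), 0 rose and 7 fell (0 and 7 adjusted over the list alone, adjusted p = 0.0152, or adjusted p = 0.234 with an estimated correlation). Olig1 had -2.80 ± 0.10. For neurons (13 tested), 1 rose and 6 fell (2 and 6 adjusted over the list alone, adjusted p = 0.0169, or adjusted p = 0.234 with an estimated correlation). For pericytes and smooth muscle (8 tested), 1 rose and 5 fell (1 and 5 adjusted over the list alone, adjusted p = 0.000149, or adjusted p = 0.156 with an estimated correlation). Acta2 had -2.28 ± 0.15.

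**Figure D4:**
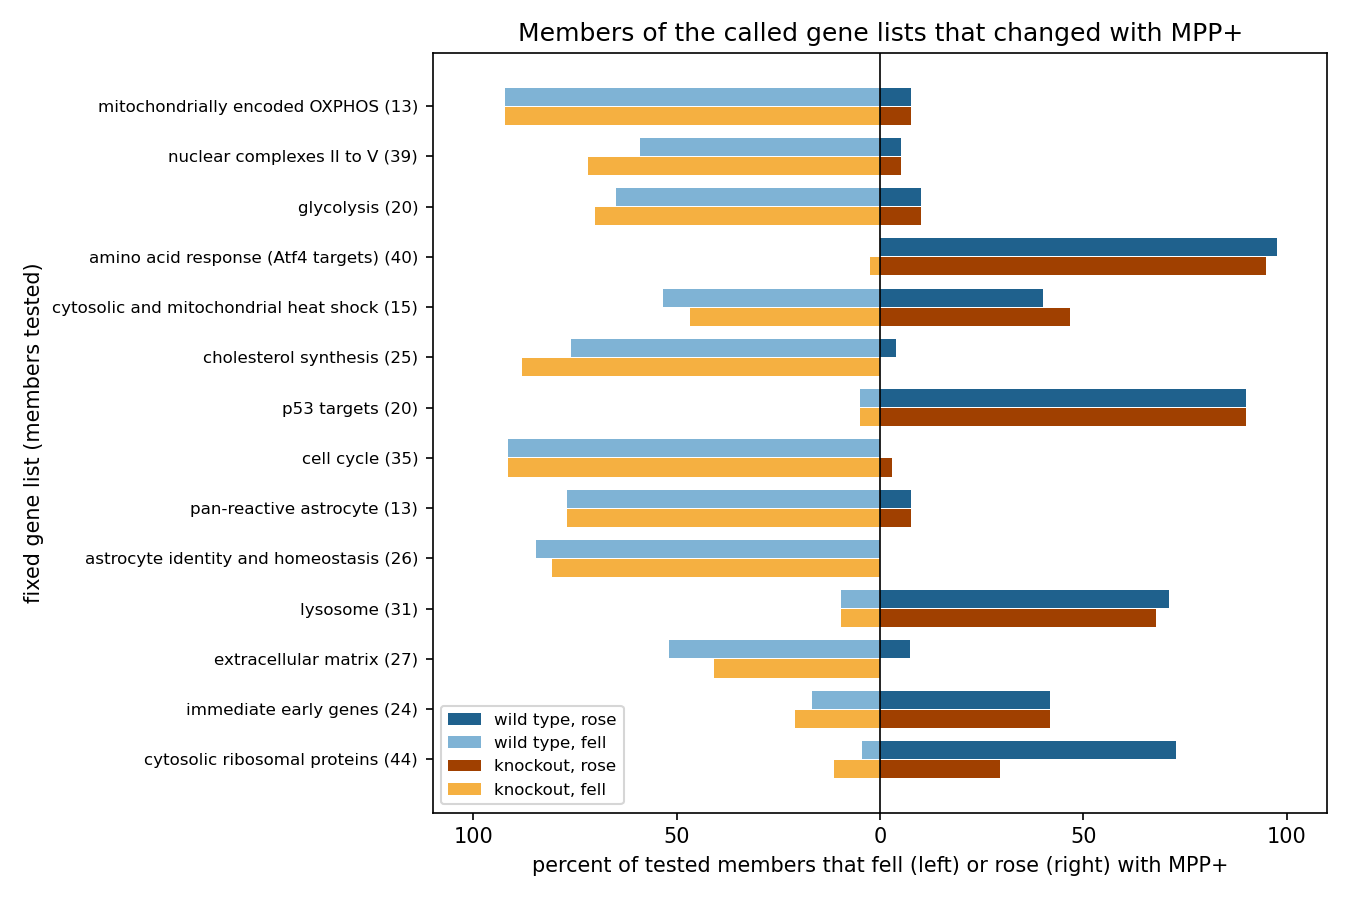
Percent of tested members that rose or fell with MPP+ in wild type and knockout, at an adjusted p under 0.05 over all genes, for the 14 functional lists called in either genotype. The Atf4 targets rose and the cell cycle genes fell in more than 90% of members in both genotypes.

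In the knockout 2 of the 12 called functional lists held with an estimated correlation, the Atf4 targets and the cell cycle genes. The heat shock list was lost without wild-type MPP+ 1 (adjusted p = 0.129) and without each knockout PBS replicate, and the matrix list without knockout MPP+ 2 (adjusted p = 0.0588). Under the alternatives heat shock was lost in 14 of 17 (adjusted p up to 0.598), the oligodendrocyte lineage in 8 of 15 (up to 0.425) and neurons in 7 of 15 (up to 0.313). Arrb2 had -0.16 ± 0.16 and Arrb1 0.60 ± 0.47, with adjusted p = 0.47 and 0.328, and for Arrb1 the value was -0.14 without knockout MPP+ 1 and past the threshold, at 1.04 (adjusted p = 0.022), without knockout MPP+ 2. Of all tested genes 59% had groups that did not overlap, where chance gives 10%.

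The comparison of knockout and wild type in PBS asked how untreated astrocytes of the genotypes differ. Igfbp7, a secreted protein that binds growth factors, was higher in the knockout with 1.86 ± 0.18, and the matrix protein fibronectin, Fn1, with 1.19 ± 0.18. Of genes that mark astrocytes, Gfap was lower with -0.90 ± 0.16 and the folate enzyme Aldh1l1 with -0.70 ± 0.090. Of genes of microglia, the Fc receptor relative Fcrls was lower with -3.42 ± 0.37 and the growth factor receptor Csf1r with -1.23 ± 0.24. In all, 2323 genes (11%) differed, 1128 higher and 1195 lower in the knockout, and 763 at least 2-fold, of which 393 were higher and 370 lower.

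The values of Elobl, AI506816, Rps2, Rps18 and Myl12b are uncertain, since reads shared with related genes or pseudogenes were not tested here. Elobl was lower in the knockout with -9.61 ± 0.36, AI506816 with -5.36 ± 0.17, and the ribosomal protein genes Rps2 and Rps18 with -4.04 ± 0.32 and -1.57 ± 0.15, while a gene model of the myosin light chain Myl12b (ENSMUSG00000117098) was higher with 6.45 ± 0.47. Of the 151 genes called with more than 8-fold, 37 (24.5%) were annotated pseudogenes, against 9.11% of the other tested genes. Serpina3n, a protease inhibitor of reactive astrocytes, was higher with 1.88 ± 0.12, and Lum, a proteoglycan of fibroblasts, with 4.47 ± 0.47.

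Of the 27 matrix genes, 8 were higher and 0 lower in the knockout (18 and 1 adjusted over the list alone, adjusted p = 4.87e-08, or adjusted p = 0.433 with an estimated correlation). The crosslinking enzyme Loxl1 had 0.67 ± 0.13. For fibroblasts and meningeal cells (14 tested, 4 of them in the matrix list too), 3 were higher and 1 lower in the knockout (5 and 1 adjusted over the list alone, adjusted p = 0.00063, or adjusted p = 0.239 with an estimated correlation). Among the 33 secreted factors of senescent cells, 16 were higher and 0 lower in the knockout (17 and 0 adjusted over the list alone, adjusted p = 2.3e-09, or adjusted p = 0.00683 with an estimated correlation), so that this list held. They included the elastase Mmp12 (2.09 ± 0.19) and the protease inhibitor Serpine2 (0.72 ± 0.087). Of the 25 genes of cholesterol synthesis, 10 were higher and 0 lower in the knockout (15 and 0 adjusted over the list alone, adjusted p = 9.64e-07, or adjusted p = 0.279 with an estimated correlation). Stard4 had 0.53 ± 0.089. Of the 24 targets of Nrf2, 5 were higher and 0 lower in the knockout (6 and 0 adjusted over the list alone, adjusted p = 0.0018, or adjusted p = 0.433 with an estimated correlation). Slc7a11 had 2.22 ± 0.24 and the quinone reductase Nqo1 0.68 ± 0.13. Of the 20 targets of p53, 5 were higher and 2 lower in the knockout (7 and 2 adjusted over the list alone, adjusted p = 0.0058, or adjusted p = 0.462 with an estimated correlation). The membrane protein Perp had 1.97 ± 0.19 and Mdm2 0.53 ± 0.087. Of the 36 nuclear subunits of complex I, 2 were higher and 0 lower in the knockout (2 and 0 adjusted over the list alone, adjusted p = 0.00146, or adjusted p = 0.462 with an estimated correlation). Of the 39 subunits of complexes II to V, 1 were higher and 0 lower in the knockout (0 and 0 adjusted over the list alone, adjusted p = 0.0352, or adjusted p = 0.76 with an estimated correlation).

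Of the 26 genes of astrocyte identity in PBS, 0 were higher and 9 lower in the knockout (2 and 10 adjusted over the list alone, adjusted p = 0.000826, or adjusted p = 0.433 with an estimated correlation). The transcription regulator Id4 had -0.74 ± 0.11. Of the 13 pan-reactive genes, 3 were higher and 2 lower in the knockout (5 and 2 adjusted over the list alone, adjusted p = 0.0235, or adjusted p = 0.433 with an estimated correlation), where Serpina3n and Gfap went apart. Of the 12 genes of the A1 reactive state, 1 were higher and 4 lower in the knockout (1 and 4 adjusted over the list alone, adjusted p = 0.0352, or adjusted p = 0.433 with an estimated correlation). Of the 17 genes of antigen presentation by class I molecules, 0 were higher and 4 lower in the knockout (0 and 6 adjusted over the list alone, adjusted p = 0.0013, or adjusted p = 0.433 with an estimated correlation). The class I molecule H2-T23 had -1.54 ± 0.20. Of the 13 genes of the inflammasome, 1 were higher and 5 lower in the knockout (1 and 6 adjusted over the list alone, adjusted p = 0.0141, or adjusted p = 0.433 with an estimated correlation). The caspase Casp4 had -1.35 ± 0.23. Beside these immune genes, all 18 tested markers of microglia and macrophages had a value below 0, and their summed level was 1580 CPM in wild type and 958 CPM in the knockout: 0 were higher and 9 lower in the knockout (0 and 14 adjusted over the list alone, adjusted p = 1.35e-11, or adjusted p = 0.174 with an estimated correlation). The leukocyte phosphatase Ptprc had -1.12 ± 0.19. For ependymal and choroid plexus cells (8 tested), 0 were higher and 5 lower in the knockout (0 and 6 adjusted over the list alone, adjusted p = 1.3e-06, or adjusted p = 0.174 with an estimated correlation). The cilia factor Foxj1 had -0.74 ± 0.12. For pericytes and smooth muscle (8 tested), 2 were higher and 0 lower in the knockout (2 and 0 adjusted over the list alone, adjusted p = 0.0168, or adjusted p = 0.229 with an estimated correlation). Of the 35 cell cycle genes, 0 were higher and 4 lower in the knockout (0 and 7 adjusted over the list alone, adjusted p = 0.00889, or adjusted p = 0.433 with an estimated correlation). Of the 14 arrestins and receptor kinases, 1 were higher and 3 lower in the knockout (1 and 4 adjusted over the list alone, adjusted p = 0.0439, or adjusted p = 0.401 with an estimated correlation). Txnip, an arrestin relative that binds thioredoxin, had -0.99 ± 0.14.

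Within 10 Mb of Arrb2, 35 of 375 tested genes (9.33%) differed in PBS, against 11% elsewhere, with an odds ratio of 0.831 (p = 0.359, two-sided Fisher's exact test, adjusted p = 0.359 over both genotype contrasts). In MPP+ 71 of 375 (18.9%) differed, against 16.8%, with an odds ratio of 1.15 (p = 0.296 by the same two-sided Fisher's exact test, adjusted p = 0.359). Of the windows tried as alternatives, 5 Mb gave odds ratios of 0.952 in PBS (p = 1, Fisher's exact test) and 1.15 in MPP+ (p = 0.436, Fisher's exact test). Within 20 Mb the odds ratio was 1.28 in PBS (p = 0.0352, Fisher's exact test) and 1.52 in MPP+ (p = 1.92e-05, Fisher's exact test). The p of both windows are unadjusted.

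The number of genes differing in PBS was 1109 without wild-type PBS 2, 1524 without wild-type PBS 3, 1248 without knockout PBS 1 and 1213 without knockout PBS 3. Lists lost without a library were complexes II to V (knockout PBS 1 and wild-type PBS 1 and 2, adjusted p up to 0.134), the cell cycle (knockout PBS 2, 0.118), pan-reactive (knockout PBS 2, wild-type PBS 3 and wild-type MPP+ 1, up to 0.132), A1 reactive (knockout PBS 1 and wild-type PBS 1, up to 0.12), arrestins and receptor kinases (wild-type PBS 1, wild-type MPP+ 2 and knockout PBS 2, up to 0.0583) and pericytes (knockout PBS 1, 0.0536). Under the alternatives pan-reactive was lost in 14 of 17 (adjusted p up to 0.432), A1 reactive in 10 of 17 (up to 0.4), arrestins and receptor kinases in 9 of 17 (up to 0.159), pericytes in 8 of 15 (up to 0.327) and the inflammasome in 7 of 15 (up to 0.528). Of the 14 called functional lists 1 held with an estimated correlation, and 33.8% of all tested genes had groups that did not overlap, where chance gives 10%.

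The comparison of knockout and wild type in MPP+ asked how the genotypes differ under the toxin. Serpina3n (2.63 ± 0.13) and the quinone reductase Nqo1 (1.63 ± 0.13) were higher in the knockout. Of genes of cell division, Pttg1, securin, was lower with -3.21 ± 0.22 and Mki67 with -1.52 ± 0.12. Col3a1, a fibrillar collagen, was higher with 3.56 ± 0.71 and the proteoglycan Lum with 5.13 ± 0.50. The class I molecule H2-Q7 was lower with -2.18 ± 0.33. In all, 3565 genes (16.9%) differed, 1663 higher and 1902 lower in the knockout, and 1071 at least 2-fold. This balance turned with the settings: 46.6% were higher, against 53.1% with no filter, 52.1% with genes of X and Y left out, chosen after seeing the data, 60.1% of those at least 2-fold, 50.2% with 2 groups only and 50.8% to 52.2% without any 1 PBS library.

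The genotype effects in both treatments had a Pearson correlation of 0.412 and a Spearman correlation of 0.332 across genes. The Pearson value was 0.137 with no filter, 0.707 with the stricter filter and 0.622 with 2 groups only. Of the genes called in PBS 84.9% had the same sign in MPP+, both calls were higher for 525 genes, where independence gives 88.8, both lower for 599, where it gives 108, and opposite for 42. Elobl (-9.52 ± 0.38) and Rps2 (-4.61 ± 0.33), whose values are uncertain, were lower again, and 40 of the 235 genes called with more than 8-fold (17.0%) were pseudogenes. Ddx3y had 45.8 CPM in the knockout against 0.0353 CPM in wild type, and Kdm5d 19.9 against 0.0202 CPM.

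Among the 24 targets of Nrf2 in MPP+, 12 were higher and 0 lower in the knockout (13 and 1 adjusted over the list alone, adjusted p = 9.02e-08, or adjusted p = 0.207 with an estimated correlation). Members that supply reducing power and glutathione were G6pdx, of the pentose phosphate pathway, with 0.62 ± 0.066, and Gclc, of glutathione synthesis, with 0.73 ± 0.085. Among the 15 heat shock genes, 6 were higher and 2 lower in the knockout (9 and 4 adjusted over the list alone, adjusted p = 0.0373, or adjusted p = 0.207 with an estimated correlation). Hspb1 had 1.05 ± 0.12 and Hsph1 0.79 ± 0.094. Among the 13 mitochondrial messenger RNAs, 5 were higher and 0 lower in the knockout (6 and 0 adjusted over the list alone, adjusted p = 0.00445, or adjusted p = 0.595 with an estimated correlation). mt-Co1 had 0.58 ± 0.080 and mt-Nd6 0.87 ± 0.12. Among the 13 pan-reactive genes, 7 were higher and 0 lower in the knockout (7 and 1 adjusted over the list alone, adjusted p = 8.41e-07, or adjusted p = 0.207 with an estimated correlation). Among the 33 senescence factors, 9 were higher and 2 lower in the knockout (11 and 4 adjusted over the list alone, adjusted p = 0.00526, or adjusted p = 0.207 with an estimated correlation). Igfbp7 had 1.61 ± 0.18. Among the 27 matrix genes, 14 were higher and 1 lower in the knockout (15 and 2 adjusted over the list alone, adjusted p = 8.94e-09, or adjusted p = 0.325 with an estimated correlation). Col6a1 had 1.03 ± 0.14 and Col5a1 1.14 ± 0.17. Beside them, for the 14 fibroblast markers, 8 were higher and 1 lower in the knockout (8 and 1 adjusted over the list alone, adjusted p = 1.8e-06, or adjusted p = 0.171 with an estimated correlation).

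Among the 20 targets of p53 in MPP+, 1 were higher and 9 lower in the knockout (1 and 13 adjusted over the list alone, adjusted p = 0.000566, or adjusted p = 0.483 with an estimated correlation). The death receptor Fas had -0.79 ± 0.11 and Zmat3 -0.40 ± 0.071, and Perp was the member that was higher, with 1.07 ± 0.19. Among the 35 cell cycle genes, 0 were higher and 14 lower in the knockout (2 and 18 adjusted over the list alone, adjusted p = 9.39e-08, or adjusted p = 0.207 with an estimated correlation). The checkpoint kinase Bub1b had -1.37 ± 0.11 and Top2a -0.93 ± 0.10. Among the 24 immediate early genes, 1 were higher and 5 lower in the knockout (1 and 7 adjusted over the list alone, adjusted p = 0.00526, or adjusted p = 0.504 with an estimated correlation). Egr1 had -0.83 ± 0.18, the phosphatase Dusp1 -0.67 ± 0.12 and the RNA decay factor Zfp36 -0.69 ± 0.13. Among the 19 genes of the JAK-STAT3 pathway, 2 were higher and 8 lower in the knockout (2 and 11 adjusted over the list alone, adjusted p = 0.0241, or adjusted p = 0.325 with an estimated correlation). The kinase Pim1 had -1.93 ± 0.35 and the cytokine Lif -0.69 ± 0.14. Among the 44 cytosolic ribosomal proteins, 0 were higher and 4 lower in the knockout (0 and 4 adjusted over the list alone, adjusted p = 0.000566, or adjusted p = 0.623 with an estimated correlation), and the lower members include Rps2, which is uncertain. Among the 17 genes of antigen presentation, 0 were higher and 9 lower in the knockout (0 and 10 adjusted over the list alone, adjusted p = 3.26e-06, or adjusted p = 0.301 with an estimated correlation). H2-T23 had -1.22 ± 0.19. Among the 13 inflammasome genes, 1 were higher and 5 lower in the knockout (1 and 5 adjusted over the list alone, adjusted p = 0.0241, or adjusted p = 0.325 with an estimated correlation). Casp4 had -1.45 ± 0.23.

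Markers of other cell types differed in MPP+ beside these groups. Microglial markers were below 0 for 16 of 18, with a summed level of 733 CPM in wild type and 436 CPM in the knockout: 0 were higher and 11 lower in the knockout (0 and 12 adjusted over the list alone, adjusted p = 6.13e-08, or adjusted p = 0.229 with an estimated correlation). Fcrls had -3.46 ± 0.37 and Csf1r -1.21 ± 0.24. For the oligodendrocyte lineage (14 tested), 3 were higher and 0 lower in the knockout (3 and 0 adjusted over the list alone, adjusted p = 0.0245, or adjusted p = 0.229 with an estimated correlation). Olig1 had 1.07 ± 0.10 and the growth factor receptor Pdgfra 2.76 ± 0.32. For neurons (13 tested), 3 were higher and 0 lower in the knockout (3 and 0 adjusted over the list alone, adjusted p = 0.0125, or adjusted p = 0.171 with an estimated correlation). Tubb3 had 1.54 ± 0.15. For ependymal and choroid plexus cells (8 tested), 0 were higher and 4 lower in the knockout (0 and 5 adjusted over the list alone, adjusted p = 0.0125, or adjusted p = 0.348 with an estimated correlation).

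The number of genes differing in MPP+ was 2025 without wild-type MPP+ 2, 2062 without wild-type MPP+ 3, 2130 without knockout MPP+ 1 and 2010 without knockout MPP+ 3. Lists lost without a library were heat shock (wild-type MPP+ 1 and 3, adjusted p up to 0.0724), the inflammasome (wild-type MPP+ 1 and knockout MPP+ 1, up to 0.146), JAK-STAT3 (knockout MPP+ 1, 0.0508), the oligodendrocyte lineage (wild-type MPP+ 2 and knockout MPP+ 3, up to 0.0826) and ependymal cells (knockout MPP+ 3, 0.0529). Under the alternatives heat shock was lost in 9 of 17 (adjusted p up to 0.164) and the inflammasome in 7 of 15 (up to 0.883). None of the 13 called functional lists held with an estimated correlation (0 lists), and 33.9% of all tested genes had groups that did not overlap, where chance gives 10%.

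The interaction asked which MPP+ effects differ between the genotypes, as knockout minus wild type. Mdm2, the p53 inhibitor, rose less in the knockout, with a difference of -0.85 ± 0.12 (adjusted p = 0.0139), and so did Plk2, a kinase that p53 induces, with -1.32 ± 0.21. The Nrf2 targets G6pdx and Gclc fell less: G6pdx had 152 CPM in PBS and 77.6 CPM in MPP+ in wild type, and 153 and 119 CPM in the knockout, a difference of 0.62 ± 0.093 (adjusted p = 0.016). Gclc had a difference of 0.79 ± 0.12 (adjusted p = 0.0161). Mki67 and Bub1b fell further, with -1.14 ± 0.16 and -1.02 ± 0.15, and of the 9 limma fits on FPKM both passed only in that with pseudocount 0.1 (adjusted p up to 0.953 and 0.251 in the others). In all, 285 genes (1.35%) passed, 127 with a difference above 0 and 158 below 0, and 109 of them at least 2-fold. This balance turned with the settings: 44.6% were above 0, against 56.8% with no filter, 54.9% with genes of X and Y left out, chosen after seeing the data, and 61.5% of those at least 2-fold.

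Single genes with the largest differences were Tenm2, an adhesion protein of synapses, which had 0.601 and 0.436 CPM in wild type in PBS and MPP+ and 0.226 and 8.03 CPM in the knockout (5.60 ± 0.53), and Rgs4, which ends signalling of G proteins (3.40 ± 0.44). Medag, a gene of fat cell formation, had 2.55 ± 0.36. Tmem56, a membrane protein, kept 56.5 and 62.4 CPM in wild type and went from 69.8 to 18.0 CPM in the knockout (-2.10 ± 0.14, adjusted p = 8.64e-05). Pttg1 had -2.49 ± 0.29 and Ifitm1, an antiviral membrane protein, -2.04 ± 0.26. Nrg1, neuregulin, rose less in the knockout (-0.83 ± 0.11). The differences for Arrb2 and Arrb1 themselves were 0.27 ± 0.23 and 1.86 ± 0.67, with adjusted p = 0.602 and 0.182, and that of Arrb1 passed without knockout MPP+ 2 (2.30, adjusted p = 0.0439).

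Of the 20 targets of p53 tested for the interaction, 0 passed the test with a difference above 0 and 3 with a difference below 0 (0 and 14 adjusted over the list alone, adjusted p = 7.67e-12, or adjusted p = 0.309 with an estimated correlation). Of the 44 cytosolic ribosomal proteins, 0 passed the test with a difference above 0 and 0 with a difference below 0 (0 and 0 adjusted over the list alone, adjusted p = 2.79e-08, or adjusted p = 0.562 with an estimated correlation). Of the 26 astrocyte genes, 2 passed the test with a difference above 0 and 0 with a difference below 0 (2 and 0 adjusted over the list alone, adjusted p = 4.45e-05, or adjusted p = 0.451 with an estimated correlation). Id4 had 1.03 ± 0.16. Of the 13 pan-reactive genes, 1 passed the test with a difference above 0 and 0 with a difference below 0 (4 and 0 adjusted over the list alone, adjusted p = 0.00294, or adjusted p = 0.365 with an estimated correlation). Of the 24 targets of Nrf2, 5 passed the test with a difference above 0 and 0 with a difference below 0 (8 and 1 adjusted over the list alone, adjusted p = 0.0195, or adjusted p = 0.58 with an estimated correlation), and the median of this list is above 0, its mean below 0 and its test upward. Of the 25 genes of cholesterol synthesis, 0 passed the test with a difference above 0 and 1 with a difference below 0 (0 and 2 adjusted over the list alone, adjusted p = 0.000364, or adjusted p = 0.365 with an estimated correlation). Of the 24 immediate early genes, 0 passed the test with a difference above 0 and 1 with a difference below 0 (0 and 3 adjusted over the list alone, adjusted p = 0.000364, or adjusted p = 0.406 with an estimated correlation). Of the 35 cell cycle genes, 0 passed the test with a difference above 0 and 3 with a difference below 0 (1 and 5 adjusted over the list alone, adjusted p = 0.00142, or adjusted p = 0.451 with an estimated correlation). This list was lost in 9 of 16 alternatives, the limma fits on FPKM (adjusted p up to 0.978), and its direction turned in that with no filter. Of the 26 inflammatory genes of NF-kappaB, 0 passed the test with a difference above 0 and 1 with a difference below 0 (0 and 5 adjusted over the list alone, adjusted p = 0.00182, or adjusted p = 0.365 with an estimated correlation). Of the 36 nuclear subunits of complex I, 0 passed the test with a difference above 0 and 3 with a difference below 0 (0 and 3 adjusted over the list alone, adjusted p = 0.00294, or adjusted p = 0.617 with an estimated correlation). Of the 33 senescence factors, 0 passed the test with a difference above 0 and 2 with a difference below 0 (1 and 6 adjusted over the list alone, adjusted p = 0.00387, or adjusted p = 0.309 with an estimated correlation). Of the 15 neurotrophic factors, 0 passed the test with a difference above 0 and 2 with a difference below 0 (2 and 4 adjusted over the list alone, adjusted p = 0.0159, or adjusted p = 0.365 with an estimated correlation). Of the 19 genes of JAK-STAT3, 0 passed the test with a difference above 0 and 0 with a difference below 0 (1 and 4 adjusted over the list alone, adjusted p = 0.0195, or adjusted p = 0.401 with an estimated correlation). Of the 8 marker lists tested 0 were called.

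**Figure D5:**
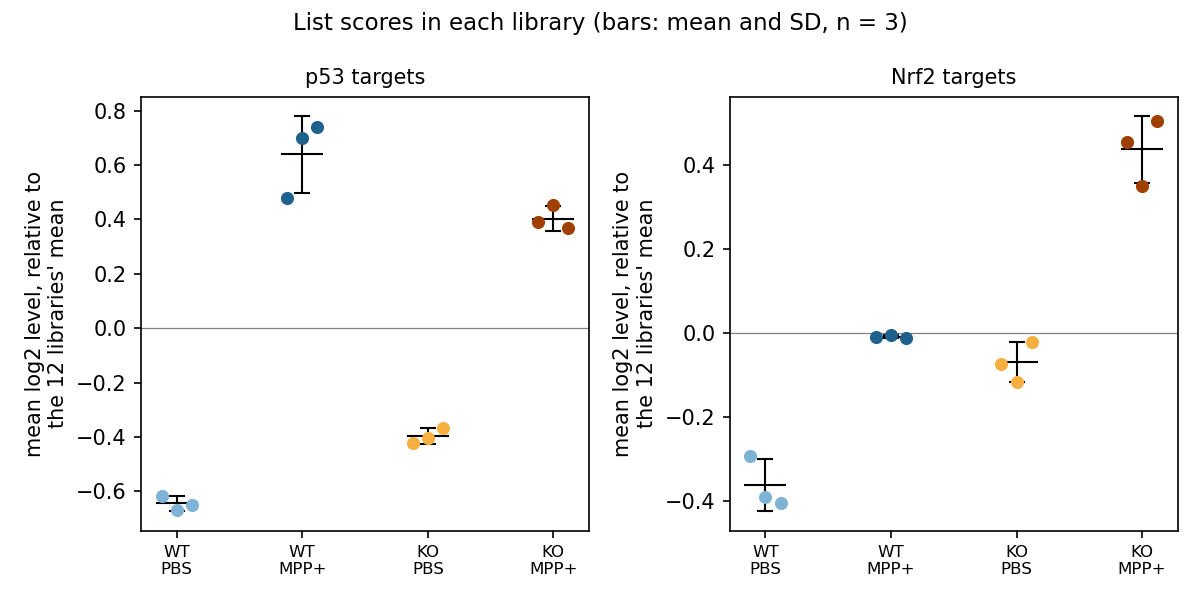
Mean log2 level of the 20 p53 targets and the 24 Nrf2 targets in each of the 12 libraries, relative to the mean of all libraries, with the mean and SD of a group. The p53 score in MPP+ is 0.479 to 0.740 in wild type and 0.368 to 0.453 in the knockout.

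The interaction count moved with single libraries: it was 1553 without wild-type MPP+ 1, 184 and 92 without knockout MPP+ 2 and 3, 98 without knockout MPP+ 1, 106 and 86 without wild-type MPP+ 2 and 3, 105, 63 and 66 without wild-type PBS 1, 2 and 3, and 92 and 63 without knockout PBS 1 and 3. It was 12 without the first replicate of both knockout groups, an alternative chosen after the data were seen that leaves 2 samples in each of these groups. The differences were then 3.30 for Rgs4, -2.06 for Ifitm1, 2.60 for Medag, 0.60 for G6pdx, 0.76 for Gclc, -0.82 for Mdm2, -1.14 for Plk2, -0.57 for Tnfrsf10b, -1.09 for Mki67, -0.83 for Bub1b, -0.77 for Nrg1 and 0.95 for Id4, none past the threshold (adjusted p from 0.0743 to 0.135), while Tmem56, Pttg1 and Tenm2 passed. Rgs4 was lost in 3 of 15 alternatives (adjusted p up to 0.084), this among them. Lists lost without a library were nuclear complex I (knockout MPP+ 3, adjusted p = 0.057), Nrf2 targets (wild-type MPP+ 1, 0.147, and knockout MPP+ 3, 0.0509), senescence factors (wild-type MPP+ 1, 0.0567), JAK-STAT3 (knockout PBS 2, 0.0524) and neurotrophic factors (wild-type MPP+ 1, 0.0838). Under the alternatives JAK-STAT3 was lost in 11 of 16 (adjusted p up to 0.297) and senescence factors in 7 of 16 (up to 0.407). Plk2 was lost without 6 libraries (wild-type PBS 3, wild-type MPP+ 3, knockout PBS 1 and 3, knockout MPP+ 1 and 3, adjusted p up to 0.056), Id4 without knockout PBS 3 (0.0503), and Tnfrsf10b, a p53 target with -0.71 ± 0.12, without 9 libraries (wild-type PBS 1, 2 and 3, wild-type MPP+ 2 and 3, knockout PBS 1 and 3, knockout MPP+ 1 and 3, adjusted p up to 0.0852).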

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

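The tests in this part of the mitochondrial RNAs, of the sex of the animals, of pseudogenes, of microglial markers, of p53 targets and without the first knockout replicates were chosen only after the results were seen, while the tests of other splits of the samples were planned. The results listed here are those whose MPP+ effect differed between the genotypes by the interaction test.

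Genes for which the MPP+ effect in the knockout was above that in wild type were Tenm2 (log2 difference 5.60), Rgs4 (3.40), Medag (2.55), Id4 (1.03), Gclc (0.79) and G6pdx (0.62). Genes for which it was below were Pttg1 (-2.49), Tmem56 (-2.10), Ifitm1 (-2.04), Plk2 (-1.32), Mki67 (-1.14), Bub1b (-1.02), Mdm2 (-0.85), Nrg1 (-0.83) and Tnfrsf10b (-0.71). Without the first replicate of both knockout groups, which leaves 2 samples in each, Tenm2, Pttg1 and Tmem56 alone of these still passed, and the others kept their sign. Lists whose MPP+ effect differed upward were astrocyte identity and homeostasis (adjusted p = 4.45e-05), pan-reactive astrocyte (adjusted p = 0.00294) and Nrf2 targets (adjusted p = 0.0195). Lists that differed downward were p53 targets (adjusted p = 7.67e-12), cytosolic ribosomal proteins (2.79e-08), cholesterol synthesis (0.000364), immediate early genes (0.000364), cell cycle (0.00142), NF-kappaB inflammatory genes (0.00182), nuclear complex I (0.00294), senescence-associated secretory factors (0.00387), neurotrophic factors (0.0159) and JAK-STAT3 pathway (0.0195). With an estimated correlation 0 of these 13 lists passed, where fry called 5.

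The first pattern is that ribosomal RNAs of the mitochondrial genome rose with MPP+ while its messenger RNAs fell. More mitochondrial RNA as a whole stays open. With MPP+ it went from 6.15 to 7.055% of counts in wild type and 6.54 to 9.63% in the knockout. Alone it would not lower the 13 messenger RNAs (log2 ratio -2.23 in wild type). Carry-over of RNA without a poly(A) tail stays open, since the RNAs tested were small and need not stand for ribosomal RNAs. Of 95 nuclear genes of such RNAs 16 rose and 1 fell in wild type (median 0.67, 95th percentile 2.90). The smallest rise of a mitochondrial ribosomal RNA in either genotype was 6.17. Open, and untested, stays a change in where transcription of the mitochondrial genome ends, in its RNA processing, in the tails of its ribosomal RNAs, or in decay. These may be effects of MPP+ on mitochondria, as a hypothesis only.

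The second pattern is the set of genes that differ between the genotypes. A lower share of astrocytes stays open. A rise of all other cell types alike is argued against. Microglia markers had a median of -0.99 in PBS, with 18 of 18 below 0 and above 1 CPM in wild type. Of 14 fibroblast markers 3 were higher and 1 lower (adjusted p = 0.239 with an estimated correlation). Sex stays open: the autosomal differences of knockout replicates 1, 2 and 3 had a median size of 1.18, 0.761 and 1.08 of the other replicates in PBS, at 0.309, 1.51 and 1.55 of their Y-linked RNA, and of 1.03, 0.84 and 1.14 in MPP+, at 0.331, 1.52 and 1.48, but over genes called with these libraries included, which favours a ratio near 1. Reads shared with pseudogenes stay open, since 3.31% of the genes called were pseudogenes, against 9.95% of the others, which says nothing of parent genes or strain variants, while among genes over 8-fold the values that sharing needs are there, with an odds ratio of 3.24. Strain and litter are not given in the labels and stay open, as does a change in fibroblasts, beside the knockout of Arrb2, whose RNA was reduced and not absent.

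The third pattern is that the list of p53 targets rose less with MPP+ in the knockout, with 3 of 20 members past the test and adjusted p = 0.309 with an estimated correlation. A single library is argued against as the cause of the call, since the highest adjusted p without any 1 library, at the preset correlation, was 1.64e-09. A smaller effect over all genes stays open: the targets lay at a median of -0.24 from the slope over all changed genes, where 10000 random lists gave -0.16 to 0.10 in 95% of cases, but the list was picked on the same values and its members go together. In PBS the p53 score was -0.669 to -0.616 in wild type and -0.423 to -0.366 in the knockout. The higher start and the lower MPP+ level both add to the pattern. A weaker p53 response in knockout astrocytes stays a hypothesis, and strain and sex stay open here too.

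Other splits of the samples were counted. For MPP+ in wild type 1 of 10 splits, the real split, gave 11667 genes, and the highest other gave 1 gene. For MPP+ in the knockout 1 of 10 gave 10083, and the highest other gave 0. For the genotypes in PBS 1 of 10 gave 2323, and the highest other gave 3, and for the genotypes in MPP+ 1 of 10 gave 3565, and the highest other gave 3. With 10 splits the share cannot be under 0.05. For the interaction 2 of 100 splits gave 285 genes or more, which does not decide whether chance is excluded, since the other splits mix the genotypes and so put their difference into the spread between samples. The highest other, with 4599 genes, exchanges the genotypes in MPP+ only and so measures the mean genotype effect, which is a structure of the samples.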

How the results depend on the processing

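Leaving out mitochondrially encoded genes, genes of X and Y, or the first replicate of both knockout groups, and some settings for the similarities and joint limma settings, were chosen after seeing the data; the other alternatives were planned. Outside single omissions, the number of genes stayed within 1.5 times in 73 cases and moved in 21, called lists kept their direction and side of the threshold in 1285 cases and lost the call in 262, and named genes kept theirs in 3042 cases and lost it in 48; where no construction is named, the cause was not tested. With fewer genes tested, the stricter filter gave 5549, 5133, 1363 and 2111 genes for MPP+ in wild type, MPP+ in the knockout, the genotypes in PBS and the genotypes in MPP+, and limma on FPKM with it 5654, 5274, 1378 and 2143. A 2-fold minimum gave 5376, 3968, 763, 1071 and, for the interaction, 109. Sample weights in limma gave 3774 in PBS and 2337 for the interaction. DESeq2 gave 1367 and no filter 148 for the interaction, and 2 groups only, with fewer samples, gave 1968 for the genotypes in MPP+. Without the first replicate of both knockout groups, with fewer samples, the genotypes gave 1012 in PBS and 1906 in MPP+, and the interaction 12. The replicate block, which takes equal numbers as a pair, gave 11607, 10040, 2453, 3646 and 217.

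Called functional lists numbered 2, 2, 1, 0 and 0 over the 5 contrasts with an estimated correlation, 24 and 24 with fry for MPP+ in the genotypes and 5 for the interaction. In PBS they numbered 9 with the stricter filter, 9 with limma with the stricter filter and 7 with quantile normalization, and in MPP+ 8 with limma with the stricter filter. Estimated correlation and fry aside, the calls lost under the most alternatives were heat shock for MPP+ in the knockout and pan-reactive in PBS (each 14 of 17, adjusted p up to 0.598 and 0.432), JAK-STAT3 of the interaction (11 of 16, up to 0.297) and A1 reactive in PBS (10 of 17, up to 0.4). The cell cycle list of the interaction, lost under 9 of 16 (up to 0.978), turned its direction in limma with no filter (adjusted p = 0.901). The Arrb2 difference in MPP+ was no longer past the threshold with no filter (-0.54), 2 groups only (-0.54), limma with no filter (-0.48), sample weights (-0.34) and the first knockout replicates left out (-0.65). Arrb1 with MPP+ in the knockout ran from -0.14 without knockout MPP+ 1 to 1.04 without knockout MPP+ 2, with -0.15 without the first knockout replicates. Its genotype difference in MPP+ ran from -0.90 without knockout MPP+ 1 to 0.28 without knockout MPP+ 2, with 0.13 without wild-type MPP+ 1 and 0.14 with sample weights. Near Arrb2, a window of 20 Mb gave p = 0.0352 in PBS, with more genes called near than elsewhere, and p = 1.92e-05 in MPP+ by Fisher's exact test.

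The correlation of MPP+ effects was 0.413 with no filter, 0.926 with the stricter filter, 0.851 with 2 groups only and 0.690 without the first knockout replicates. In limma it was 0.908, with pseudocount 0.1 0.898, no filter 0.892, stricter filter 0.924, median-ratio rescaling 0.908, quantile normalization 0.905, the replicate block 0.908, no trend 0.908 and sample weights 0.895. The correlation of genotype effects was, in the same order, 0.137, 0.707, 0.622 and 0.344, and in limma 0.625, 0.627, 0.588, 0.667, 0.626, 0.622, 0.625, 0.625 and 0.589.

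With each library left out, numbers of genes ran from 10572 to 11660, 8972 to 10495, 1109 to 2753 (the lowest without wild-type PBS 2), 2010 to 4746 (without knockout MPP+ 3) and, for the interaction, 63 (without wild-type PBS 2 and without knockout PBS 3) to 1553 (without wild-type MPP+ 1). Called lists ran from 12 to 13, 11 to 13, 12 to 16, 12 to 14 and 11 to 15. The Arrb2 difference ran from -0.97 to -0.72 in PBS and -0.67 to -0.39 in MPP+, and the correlations from 0.681 to 0.700 and 0.329 to 0.357. An omission leaves a smallest group of 2, so more low-count genes pass the filter.

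The share of called genes that were higher moved by more than 10 points in these cases. In PBS it was 48.6% in edgeR and in limma 34.3%, with pseudocount 0.1 34.4%, no filter 35.7%, stricter filter 37.5%, the replicate block 35.8%, no trend 33.7% and sample weights 35.3%, but 45.7% with median-ratio rescaling and 43.7% with quantile normalization. Limma with the stricter filter gave 60.0% and 61.6% for MPP+ in wild type and knockout, where edgeR gave 48.5% and 48.3%, and it moved the median of all genes to 0.13 and 0.12. The 2-fold minimum gave 37.5%, 33.2%, 60.1% in the genotypes in MPP+ and 61.5% for the interaction. The interaction, at 44.6%, had 56.8% with no filter, 58.0% with sample weights, 55.4% with median-ratio rescaling and with no trend, 54.9% with genes of X and Y left out (251 of the 285 genes were shared, 0 with opposite sign) and 58.3% without the first knockout replicates. It had 55.6% and 62.1% without wild-type PBS 2 and 3, 59.3% without wild-type MPP+ 3, 58.7% and 61.9% without knockout PBS 1 and 3, and 55.4% without knockout MPP+ 2. Depth limits genes near 0: a floor of 3 counts over a group is 0.0144 to 0.0151 CPM.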

Other observations

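Of the lists that camera did not call with MPP+ in wild type, many members changed. Among the 18 endoplasmic reticulum chaperones, which fold secreted proteins, 6 rose and 10 fell (6 and 10 adjusted over the list alone, adjusted p = 0.616). Among the 19 genes of the hypoxia response, to which Vegfa belongs, 5 rose and 8 fell (5 and 8 adjusted over the list alone, adjusted p = 0.49), with a median and mean below 0 and an upward test. Among the 25 autophagy genes, 15 rose and 3 fell (15 and 4 adjusted over the list alone, adjusted p = 0.155), and among the 25 genes of mitophagy and mitochondrial dynamics, which clear and divide mitochondria, 9 rose and 6 fell (10 and 6 adjusted over the list alone, adjusted p = 0.737). Of 291 KEGG pathways given in the deposited table, tested after the data were seen, camera called 39 in this contrast, and 0 with an estimated correlation. That of autophagy was among the 39, with 58 of 119 members that rose and 18 that fell (adjusted p = 0.00707, or adjusted p = 0.161 with an estimated correlation).

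Immune, reactive and other lists follow. Among the 32 genes of the interferon response, 9 rose and 4 fell (7 and 2 adjusted over the list alone, adjusted p = 0.425). Among the 16 complement genes, 3 rose and 8 fell (3 and 8 adjusted over the list alone, adjusted p = 0.122). Of the 12 genes of the A2 reactive state, 3 rose and 3 fell (3 and 3 adjusted over the list alone, adjusted p = 0.769), with a median above 0 and a mean below 0. Of the 7 genes of dopamine receptors, monoamine metabolism and MPP+ transport, 3 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.616), with a median and mean below 0 and an upward test. Of the 8 endothelial markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone, adjusted p = 0.434). Apart from the KEGG pathway, the lists in these paragraphs were not called by camera in any of the 5 contrasts. In wild type with MPP+, fry called autophagy (adjusted p = 8.41e-06), complement (2.44e-05), hypoxia (0.0055), dopamine receptors with MPP+ transport (0.00856), endothelial markers (0.00962) and endoplasmic reticulum chaperones (0.0135). In the knockout it called mitophagy (0.00853) and the A2 genes (0.0071) as well. Red blood cell markers had 2 tested members, under the minimum of 5.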
